A study of Mus musculus with 6 samples.

How the data were processed

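The series measured gene expression in 6 Affymetrix whole-genome mouse expression arrays, each hybridised with RNA from a pool of sorted cells of about 15 mice. Per the labels, 3 arrays carried reactive astrocytes and 3 carried non-reactive astrocytes. Both groups were FVB/N mice of 2 to 3 months, and the sex of the animals was not determined. The cells were sorted for green fluorescence after dead cells, doublets and autofluorescent cells had been gated out. RNA was isolated with a micro column kit and amplified and biotin-labelled in 2 rounds, per the labels' protocols.

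The deposited values are log2 expression values made by the authors with RMA (robust multi-array average), per the submitters' processing notes. The version of RMA, its background setting and the set of arrays normalised together are not given in the sources used here. RMA in its usual form corrects the background, quantile-normalises the arrays and summarises the probes of each probe set. The 6 array medians lay between 4.65 and 4.73 on the log2 scale. Equalised distributions hide any change in the total RNA of a cell, and values near the maximum are compressed.

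Each array held 45101 probe sets. The 64 control probe sets were left out of the tests, which left 45037. The platform annotation gave exactly 1 gene symbol for 34945 of these, several for 932 and none for 9160. The gene identifiers of 34741 probe sets matched a mouse gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used only for names. No coordinates are printed because the array files name no genome build. A gene was represented by the probe set with the highest mean over the 6 arrays among those with 1 symbol, which gave 18193 genes. No gene was named from a probe set with several symbols.

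Before the data were examined, the comparison, its test, the gene lists, the rule for named genes and the alternatives were fixed, except 1 alternative on the lists that was added later. The comparison was reactive minus non-reactive, fitted on all 6 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates. Tests were two-sided, with Benjamini-Hochberg adjustment over the 45037 probe sets and a threshold of 0.05. A size limit of 2-fold was applied separately. Errors printed beside log2 fold changes are moderated standard errors, and intervals have a confidence level of 95%. The same fit estimated 2.68 prior degrees of freedom and a prior SD of 0.337.

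The 37 gene lists held 700 different genes, of which 645 were measured. They covered galectins, enzymes of galectin ligand glycans, integrins, reactive astrocyte gene sets of the pan-reactive, A1 and A2 types, astrocyte transport and identity, cell cycle, extracellular matrix, proteoglycans, cytoskeleton, lipid and energy metabolism, antigen presentation, interferon response, complement, cytokines, Notch and Sonic hedgehog signalling, progenitor genes, oxidative stress, phagocytosis, synapse-regulating factors, immediate early genes, the neighbours of Aldh1l1 and markers of 10 other cell types. Each list with at least 5 measured members was tested with limma's camera against all other named genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The same lists were also tested with an estimated correlation and with fry. For each list, p-values were also adjusted over the list alone.

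The named genes followed a rule. It took every measured galectin, Gfap and Aldh1l1, then the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap. From each list it took up to 4 members past the threshold with the largest change and up to 2 others with the highest mean. Genes named outside the rule are stated as chosen after their values were seen. Not every bright member that missed the threshold is printed.

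The alternatives for scaling and fit were another quantile normalisation, median centring, cyclic loess, eBayes with a trend or robust, and array weights. Others removed probe sets with means below the median of 4.74, or took the mean of a gene's probe sets. A further one removed 8955 probe sets by suffix for possible cross-hybridisation. The suffixes removed were _x_at, _s_at and _a_at, of which _a_at alone need not mean that a probe set reads other genes. The rest were the replicate number as a block, each array left out in turn, a test against a 1.5-fold change, and the other list tests.

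The fit was tested on simulated data for the 45037 probe sets with their real means and spreads. The noise was independent between probe sets and had 1 spread for both groups. Known changes of 2-fold, 4-fold and 8-fold were added to 67, 67 and 66 probe sets. Of those changed 2-fold 0% were called, of those changed 4-fold 31.3% and of those changed 8-fold 72.7%. Of 79 calls, 10 fell on probe sets that had not been changed. With nothing changed there were 0 calls. The labels describe the arrays as biological replicates made from pools of animals, so the p-values measure the spread between pools and not between animals. The number of arrays limits the precision.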

Results

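Gene expression was measured on 6 arrays of green fluorescent cells sorted from the grey matter of the mouse somatosensory cortex, in a series that asked about galectin-1 and galectin-3 in injured brain tissue. The 3 reactive samples came from GFAP-eGFP mice, in which a human GFAP promoter drives the fluorescent protein, taken 5 days after a stab wound 0.7 mm deep and 1 to 1.2 mm long. The 3 non-reactive samples came from the corresponding region of uninjured Aldh1l1-eGFP mice. Injury and reporter line therefore coincided, and no array of either line was present in the other group, so a difference between the groups cannot be assigned to either. The correlation between arrays was 0.901 to 0.921 within the reactive group, 0.95 to 0.963 within the non-reactive group and 0.889 to 0.93 between the groups. The first principal component held 37.1% of the variance and separated the groups, with scores of -102.2 to -44.9 in the reactive and 62.6 to 78.8 in the non-reactive arrays. The next component held 23.4% and set reactive replicate 3, at -99.3, apart from the other reactive arrays at 77.95 and 57.1.

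The first question was whether the galectins named in the series title differed between the groups. Lgals3, which encodes galectin-3, a carbohydrate-binding protein of macrophages and reactive glia, rose 33.5-fold, from 4.92 ± 0.51 to 9.99 ± 1.36 (log2, SD, n = 3). The non-reactive mean lay close to 4.74, the median of all probe set means, so the size of this rise is uncertain. The log2 fold change was 5.07 with a standard error of 0.67, and limma gave an adjusted p of 0.0373 after Benjamini-Hochberg correction. The arrays of the 2 groups did not overlap. Lgals1, which encodes galectin-1, measured 12.88 ± 0.87 in the reactive and 11.30 ± 0.18 in the non-reactive arrays, a log2 difference of 1.58 (SE 0.43, 95% interval 0.54 to 2.62). It did not pass over all probe sets (limma adjusted p = 0.196). The other Lgals1 probe set differed by 2.64 (SE 0.46) with a limma adjusted p of 0.0666.

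Among the 10 measured genes of the galectin list, 1 rose over all probe sets and 2 adjusted over the list alone, Lgals3 and Lgals1. Lgals8 differed by -1.67 (SE 0.62), Lgalsl by -0.96 (SE 0.69), Lgals4 by -0.92 (SE 0.47) and Lgals3bp by 0.56 (SE 0.24), and none of them passed. Lgals8 differed by -0.80 with the mean of its probe sets, of which the other was at 0.08, and by -0.97 without reactive replicate 1. Without reactive replicate 3 Lgalsl differed by -0.15, and without non-reactive replicate 2 Lgals4 differed by -0.41. Lgals12 differed by 0.28, Lgals9 by -0.17, Lgals2 by -0.12 and Lgals7 by -0.04. The list as a whole was not shifted (limma camera, adjusted p = 0.898), and its median log2 fold change of -0.08 had the opposite sign to its mean of 0.36 and to camera's direction, which was up. The marker list of microglia and macrophages, cells that express Lgals3, was higher on the same reactive arrays, as given with its values further on. The call for Lgals3 was lost without reactive replicate 1 (limma adjusted p = 0.0898) and without non-reactive replicate 1 (0.132), 2 (0.138) or 3 (0.108), and with the replicate number as a block (0.105), within a range of 0.0282 to 0.138 over the alternatives.

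**Figure D1:**
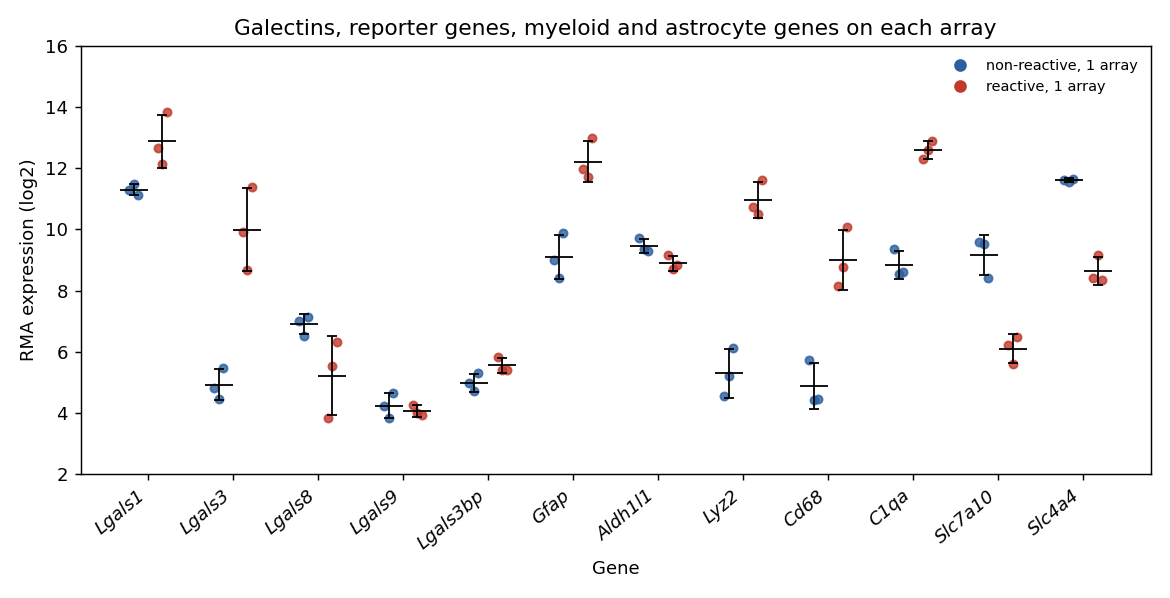
RMA expression on the log2 scale of 12 genes on each array, with 3 non-reactive and 3 reactive arrays per gene and bars for the mean and SD. Lgals3 lies at 4.92 in the non-reactive and 9.99 in the reactive group, and Slc4a4 at 11.61 and 8.63.

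Gfap and Aldh1l1, whose regulatory sequences drive the reporters, were measured as endogenous transcripts. The reactive cells were sorted for fluorescence driven by a GFAP promoter, so the sort itself could select cells with high Gfap. A difference in Gfap therefore cannot be assigned to reactivity, here or in the lists that hold it. Gfap, the intermediate filament of astrocytes, rose 8.71-fold, from 9.10 ± 0.74 to 12.22 ± 0.67 (log2, SD, n = 3, limma adjusted p = 0.0492). Of its other probe sets, 1 rose by 2.34 (limma adjusted p = 0.0497) and 1 differed by 2.18 (adjusted p = 0.246). Its call held in 3 of 16 alternatives, over which the limma adjusted p ran from 0.0394 to 0.263. Aldh1l1, a folate enzyme of astrocytes, measured 8.89 ± 0.24 and 9.46 ± 0.23 and did not pass (log2 difference -0.57, limma adjusted p = 0.366). The 7 measured neighbours of Aldh1l1 on its chromosome were not shifted (camera adjusted p = 0.857); Klf15 differed by 0.14 and Slc41a3 by 0.06.

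The largest rises over all genes included those of Lyz1 and Lyz2, near-identical lysozyme genes, at 5.85 (SE 0.44) and 5.67 (SE 0.47) on the log2 scale. Which of the lysozyme genes a probe set reads is uncertain. Ifitm3, an interferon-induced membrane protein, rose by 5.28, Cyba, a subunit of the phagocyte oxidase, by 5.16, Emp3 by 4.39, Cd68, a lysosomal protein of macrophages, by 4.12 and Cd14, a lipopolysaccharide co-receptor, by 4.10. Ifi27l2a rose by 4.08, the complement genes C1qc and C1qa by 3.81 and 3.76, and Pycard, an inflammasome adaptor, by 3.59. The largest falls were 26.0-fold for Timp3, a metalloproteinase inhibitor, 22.7-fold for Nat8f3, 19.5-fold for the matricellular gene Ccn1, 12.8-fold for Mtm1 and 12.3-fold for Adhfe1. Rorb fell 11.1-fold, Soga3 10.4-fold, Kdm5b 9.98-fold, F3, the tissue factor gene, 9.80-fold, Lix1 9.20-fold, Ubr2 9.03-fold and Slc7a10 8.40-fold. The limma adjusted p of these genes lay at or below 0.0497. Timp3 was measured by 4 probe sets, whose log2 fold changes were -0.74, -1.33, -2.25 and -4.70. The reactive means of Nat8f3, Ccn1, Mtm1 and Soga3 (4.45, 4.09, 4.29 and 3.96) and the non-reactive mean of Emp3 (3.65) lay below 4.74, the median of all probe set means, so the size and order of these changes are uncertain. The values of genes with several probe sets depended on the probe set. With the mean of a gene's probe sets, 15 of the 55 named genes that passed moved by more than 1.5 times, among them Nat8f3 to -2.33, Ccn1 to -2.67, Mtm1 to -1.44, Adhfe1 to -1.28, Rorb to -1.63, Soga3 to -1.40, Kdm5b to -1.32, Ubr2 to -0.98, Timp3 to -2.25 and Pycard to 1.41. Without probe sets open to cross-hybridisation Lyz1 differed by 0.60 and Adhfe1 by -0.58. Without non-reactive replicate 1, 2 or 3 another probe set represented Ccn1, at -1.40, -1.32 and -0.91, while its first probe set gave -4.48, -4.39 and -3.98, and neither passed.

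In all, 173 of 18193 genes passed, of which 71 rose and 102 fell (limma, Benjamini-Hochberg). At the level of probe sets, 383 of 45037 passed, of which 120 rose and 263 fell. All 173 genes changed at least 2-fold, and all had groups that did not overlap. Chance gives such groups for 10% of genes, but the calls rest on the same values, so the lack of overlap is no separate support. At an unadjusted p under 0.05 there were 2730 genes. The gene count was 22 without reactive replicate 1, 73 without reactive replicate 2, 77 without reactive replicate 3 and 0 without any 1 of the non-reactive arrays, where 1898 to 2133 genes had an unadjusted p under 0.05. With the replicate number as a block limma called 0 genes, with 2401 at an unadjusted p under 0.05. Of the 55 named genes that passed with limma, 5 kept their call without reactive replicate 1, 18 without reactive replicate 2 and 24 without reactive replicate 3, and 0 without any 1 of the non-reactive arrays. All 55 kept their sign in each of these. A test against a 1.5-fold change called 14 genes.

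Genes of astrocyte transport and identity were lower in the reactive arrays. Slc4a4, a bicarbonate cotransporter, fell 7.89-fold, from 11.61 ± 0.05 to 8.63 ± 0.46 (log2, SD, n = 3). Slc7a10, an amino acid transporter, fell by 3.07 on the log2 scale, the zinc transporter Slc39a12 by 2.83, the gap junction gene Gjb6 by 2.63 and the metabotropic glutamate receptor Grm3 by 1.89. Of 20 measured transport genes 6 fell, and 13 fell adjusted over the list alone. Slc1a2, a glutamate transporter, differed by -2.16 (SE 0.44) and Glul, glutamine synthetase, by -0.32 (SE 0.18), and neither passed. Of 23 identity genes 4 fell and 1, Gfap, rose, against 16 and 1 adjusted over the list alone. Gpc5 fell by 2.82 and S1pr1 by 2.48, while Aldoc differed by -1.11 and Apoe by 0.10 without passing. With the mean of a gene's probe sets Slc4a4 differed by -1.66 and Slc39a12 fell by 1.48. Limma's camera called both lists lower, with adjusted p of 8.01e-14 for transport and 3.89e-16 for identity. With an estimated correlation both had an adjusted p = 0.0548. On the same reactive arrays camera called the marker lists of microglia and macrophages (2.21e-14) and of oligodendrocytes (1.03e-05) higher. The 3′ minus 5′ differences of the Gapdh, Actb and Pcx controls differed between the groups by -1.03, -1.66 and -2.02, and that of the 18S rRNA controls by 1.98.

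Gene sets linked to astrocyte reactivity were higher. All 13 measured pan-reactive genes had log2 fold changes above 0, of which 1, Gfap, rose over all probe sets and 5 adjusted over the list alone. Since the reactive cells were sorted through a GFAP promoter, the call for Gfap is no separate support for reactivity. Serpina3n, a secreted serine protease inhibitor, differed by 1.43 (SE 0.55) without passing. Vim, the filament vimentin, differed by 2.59 at its representative probe set (limma adjusted p = 0.0512), and its 2 other probe sets rose by 3.40 and 3.81. The non-reactive mean of the last, 3.85, lay below 4.74, the median of all probe set means, so its size is uncertain. The list score per array was 0.08, 0.77 and 1.82 in reactive replicates 1, 2 and 3. Camera called the list higher with an adjusted p of 9.48e-06, and the adjusted p = 0.155 with an estimated correlation. Timp1, chosen after its values were seen, differed by 3.71 (SE 0.78) without passing. Its non-reactive mean of 4.005 lay below 4.74, the median of all probe set means, so this size is uncertain.

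Of 13 A1-type genes listed 9 were measured, and C3, H2-T23, Ggta1 and Ugt1a1 were not among them. Of the 9, 2 rose, H2-D1 by 3.38 and Srgn, a proteoglycan of blood cell granules, 6.94-fold, and 5 rose adjusted over the list alone. Without probe sets open to cross-hybridisation H2-D1 differed by 0.82, and with the mean of its probe sets by 1.29. Psmb8 differed by 2.06 and Fkbp5 by 1.56. Of 13 A2-type genes 1 rose, Cd14, also when adjusted over the list alone; S100a10 differed by 1.56 and Stat3 by 0.42. Camera called both lists higher (adjusted p of 7.12e-05 for A1 and 0.000778 for A2), with an adjusted p = 0.0698 for A1 and adjusted p = 0.246 for A2 with an estimated correlation. Of 31 cytoskeletal genes 2 rose, Anxa3 by 3.36 and Gfap, and 6 adjusted over the list alone, while Tmsb10 differed by 0.32 and Actb by -0.08. Camera called that list higher (adjusted p of 0.000112), with an adjusted p = 0.44 with an estimated correlation and 0.106 with fry, in a range of 2.05e-06 to 0.44 over the alternatives. Its list score was -0.02 in reactive replicate 1 and 1.18 in reactive replicate 3. Camera called myeloid markers (2.21e-14) and oligodendrocyte markers (1.03e-05) higher on the same arrays as these lists. The 3′ minus 5′ control difference was lower for Gapdh (4.17 against 5.19), Actb (3.38 against 5.05) and Pcx (1.44 against 3.46). That of 18S rRNA was higher (0.83 against -1.15).

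Of 23 microglia and macrophage markers 7 rose and none fell, and 15 rose adjusted over the list alone. Besides C1qa, C1qc and Cd68, Fcer1g, an Fc receptor chain, rose by 2.73, from 6.52 ± 0.46 to 9.25 ± 0.72 (log2, SD, n = 3). The bright markers Ctss and Csf1r differed by 1.52 (SE 0.26) and 0.42 (SE 0.25) without passing. Cx3cr1, a receptor of resident microglia chosen after its values were seen, measured 9.73 ± 0.28 and 9.70 ± 0.51. Camera called these markers higher with an adjusted p of 2.21e-14, and the adjusted p = 0.0548 with an estimated correlation. Of 21 blood leukocyte markers 4 rose, also when adjusted over the list alone, Lyz1, Lyz2, Cd52 by 3.52 and Plac8 by 3.31. The non-reactive mean of Plac8, 4.36, lay below 4.74, the median of all probe set means, so its size is uncertain. The T cell genes Cd3e and Cd3d differed by 0.15 and 0.03. Lyz1 and Lyz2 are near-identical and may give the same signal. The median log2 fold change of the leukocyte list was 0.17. This list had a camera adjusted p of 0.00451, and an adjusted p = 0.359 with an estimated correlation.

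Antigen presentation and interferon genes were higher beside these markers. Of 12 MHC class I genes 2 rose, B2m, the class I light chain, by 3.06 and H2-D1, and 8 rose adjusted over the list alone; H2-K1 differed by 2.67 and Psmb10 by 1.08. That list had a camera adjusted p of 5.36e-06, and the adjusted p = 0.0564 with an estimated correlation. Of 23 interferon-stimulated genes 2 rose, Ifitm3 and Oas1a by 2.30, and 6 adjusted over the list alone, while Ifi35 differed by 1.81 and Irf1 by 0.64. Its camera adjusted p was 2.74e-05, with an adjusted p = 0.0564 with an estimated correlation. Of 12 complement genes C1qa and C1qc rose and Clu, clusterin, fell by 1.89, against 4 and 1 adjusted over the list alone. C1qb differed by 1.77 and Cd59a by -0.47. The complement list had a camera adjusted p of 0.024, and an adjusted p = 0.155 with an estimated correlation. Without its myeloid markers, an alternative chosen after seeing the data, its adjusted p was 0.821, in a range of 0.000646 to 0.821. Oligodendrocyte markers were also called higher on the reactive arrays (camera, 1.03e-05). The 3′ minus 5′ control difference was lower for Gapdh (4.17 against 5.19), Actb (3.38 against 5.05) and Pcx (1.44 against 3.46). That of 18S rRNA was higher (0.83 against -1.15).

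Of 32 cytokine and growth factor genes, Ccl4, a chemokine, rose by 2.91, Il1b by 2.07 and Cxcl1 by 1.51, and Vegfa fell by 1.82. Cxcl1 rose by 2.46 with the mean of its probe sets and differed by 2.81 without probe sets open to cross-hybridisation. Adjusted over the list alone 4 rose and 2 fell. Cxcl14 differed by -1.16 and Il18 by -1.06, and the list was not shifted (camera adjusted p = 0.197). Of 22 immediate early and heat shock genes, Gadd45b rose 6.52-fold, Egr2 3.72-fold and Junb 3.63-fold, and 7 rose adjusted over the list alone, while Egr1 differed by -0.37 and Hspa8 by 0.03. Camera called this list higher with an adjusted p of 0.0111, and an adjusted p = 0.252 with an estimated correlation. Its call was lost without probe sets open to cross-hybridisation (adjusted p = 0.0938), without reactive replicate 2 (0.0598) and without non-reactive replicate 1 (0.0602), in a range of 0.00131 to 0.252 over the alternatives. Microglia and macrophage markers (2.21e-14) and oligodendrocyte markers (1.03e-05) were called higher by camera on the same reactive arrays. The 3′ minus 5′ control difference was lower for Gapdh (4.17 against 5.19), Actb (3.38 against 5.05) and Pcx (1.44 against 3.46). That of 18S rRNA was higher (0.83 against -1.15).

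Lipid metabolism genes were lower. Of 21 fatty acid oxidation genes 1 fell, Acsl6, an acyl-CoA synthetase, by 3.05 on the log2 scale, and 7 fell adjusted over the list alone. Hadhb differed by -1.06 and Hadh by -0.56. Of 19 cholesterol synthesis genes none passed over all probe sets and 7 fell adjusted over the list alone, with Fdft1 at -1.22 (SE 0.23) and Hmgcs1 at -0.69 (SE 0.19). Camera called both lists lower, with adjusted p of 7.26e-08 for oxidation and 2.05e-06 for cholesterol. With an estimated correlation the adjusted p = 0.154 for oxidation and the adjusted p = 0.104 for cholesterol. Of 17 glycolysis genes Ldhb, a lactate dehydrogenase subunit, fell by 1.36, also when adjusted over the list alone, with Aldoc at -1.11 and Pgk1 at -0.09. That list was not shifted (camera adjusted p = 0.541), and its mean of 0.01 had the opposite sign to its median of -0.04 and to camera's direction, which was down. On the same reactive arrays the marker lists of microglia and macrophages and of oligodendrocytes were called higher by camera (adjusted p of 2.21e-14 and 1.03e-05). The 3′ minus 5′ control difference was lower for Gapdh (4.17 against 5.19), Actb (3.38 against 5.05) and Pcx (1.44 against 3.46). That of 18S rRNA was higher (0.83 against -1.15).

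Signalling lists also moved. Of 11 Sonic hedgehog genes Gli3, a transcription factor of the pathway, fell by 2.07, and 6 fell adjusted over the list alone, while Ptch1 differed by -2.69 (SE 0.65) and Gas1 by -2.14. The camera adjusted p was 0.00142, and the adjusted p = 0.155 with an estimated correlation. Of 18 Notch genes Nrarp, a target gene of the pathway, fell by 2.04, against 3 fallen and 1 risen adjusted over the list alone, while Hes5 differed by -1.30 and Rfng by -0.60. The camera adjusted p was 0.0268, and the adjusted p = 0.155 with an estimated correlation. The Notch call held in 12 of 19 alternatives; it was lost with cyclic loess (0.0583), with dim probe sets dropped (0.0776), with the mean of a gene's probe sets (0.109), with the replicate number as a block (0.0522) and without reactive replicate 2 (0.0901) or non-reactive replicate 2 (0.0663), in a range of 0.00648 to 0.155. None of 21 proteoglycan genes passed and 3 fell adjusted over the list alone, with Ptprz1 at -2.23 (SE 0.38) and Bcan at -1.87 (SE 0.36). Camera called that list lower with an adjusted p of 0.0195, although its median was 0.03, and the adjusted p = 0.155 with an estimated correlation. Without reactive replicate 2 its adjusted p was 0.0683 and with the mean of a gene's probe sets 0.0606, in a range of 0.0156 to 0.155. Beside these 3 lists, microglia and macrophage markers (2.21e-14) and oligodendrocyte markers (1.03e-05) were called higher by camera. The 3′ minus 5′ control difference was lower for Gapdh (4.17 against 5.19), Actb (3.38 against 5.05) and Pcx (1.44 against 3.46). That of 18S rRNA was higher (0.83 against -1.15).

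Cell cycle genes were higher mainly on 1 array. None of 35 passed and 1 rose adjusted over the list alone, with Ccnd1 at 1.73 (SE 0.55) and Mcm7 at 0.41. Rrm2, a ribonucleotide reductase subunit chosen after its values were seen, differed by 4.42 (SE 0.83, limma adjusted p = 0.0814). Its non-reactive mean of 3.18 lay below 4.74, the median of all probe set means, so this size is uncertain. The list score was 0.17, -0.17 and 1.34 in reactive replicates 1, 2 and 3. Camera called the list higher (adjusted p of 0.000148), with an adjusted p = 0.464 with an estimated correlation. Without reactive replicate 3 the adjusted p was 0.0697 and with fry 0.26, in a range of 3.81e-06 to 0.464. Of 37 extracellular matrix genes Timp3 fell, and 3 rose and 1 fell adjusted over the list alone; Timp2 differed by 2.28 and Sparc by 0.25. The matrix list was not shifted (camera adjusted p = 0.352), and its score was 0.84 in reactive replicate 3 against -0.12 and -0.15 in the other reactive arrays. The endothelial and fibroblast scores of reactive replicate 3 were 0.98 and 1.13, against -0.02 and -0.15 in replicate 1 and -0.13 and -0.23 in replicate 2. Microglia and macrophage markers (2.21e-14) and oligodendrocyte markers (1.03e-05) were called higher by camera on the reactive arrays. The 3′ minus 5′ control difference was lower for Gapdh (4.17 against 5.19), Actb (3.38 against 5.05) and Pcx (1.44 against 3.46). That of 18S rRNA was higher (0.83 against -1.15).

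Among markers of other cell types, 2 of 15 oligodendrocyte genes rose, Gpr37 by 2.37 and Ermn by 2.17, while Cnp differed by 1.04 and Mbp, the main myelin transcript, by -0.49. Adjusted over the list alone 10 rose and 1 fell. Camera called these markers higher at 1.03e-05, and the adjusted p = 0.252 with an estimated correlation. Progenitor markers were called higher at an adjusted p of 0.024, with an adjusted p = 0.33 with an estimated correlation, and with Olig1 at 0.94 and Sox10 at 0.88. That call was lost with fry (0.106), without probe sets open to cross-hybridisation (0.0598) and without reactive replicate 2 (0.159) or 3 (0.0589), and without non-reactive replicate 1 (0.0559) or 2 (0.116), in a range of 0.00169 to 0.33. None of the 13 progenitor markers passed, and 1 rose adjusted over the list alone. None of 12 ependymal markers passed either way, with Mia at 1.41 and Rarres2 at -0.02, at a camera adjusted p of 0.00098 and an adjusted p = 0.155 with an estimated correlation. Camk2a and Rbfox3, the neuronal markers with the highest means, differed by -0.44 and -0.30, and Camk2a measured 12.63 ± 0.35 in the reactive and 13.07 ± 0.14 in the non-reactive arrays.

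No gene of the endothelial, pericyte, fibroblast, neuronal or erythrocyte lists passed, and none adjusted over the list alone. Their camera adjusted p were 0.102, 0.821, 0.117, 0.355 and 0.877. Itm2a of the endothelial list differed by 2.83 (SE 0.62) and Egfl7 by 0.87, Pdgfrb of the pericyte list by -2.24 (SE 0.80), Ptgds of the fibroblast list by 0.81 and Hbb-b2 of the erythrocyte list by 0.09. Without reactive replicate 1 the camera adjusted p was 0.0398 for endothelium and 0.0479 for fibroblasts. Without reactive replicate 2 it was 0.0263 for endothelium, 0.0497 for fibroblasts and 0.0212, in the lower direction, for neurons. Without non-reactive replicate 2 it was 0.0163 for endothelium, with the mean of a gene's probe sets 0.0213 for endothelium, and without probe sets open to cross-hybridisation 0.0418 for fibroblasts. The ranges over the alternatives were 0.0163 to 0.678 for endothelium, 0.0418 to 0.803 for fibroblasts and 0.0212 to 0.978 for neurons.

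The remaining lists were not shifted. Of 22 progenitor and stem cell genes Pax6, a transcription factor, fell by 1.48, and 3 rose and 7 fell adjusted over the list alone, with Fabp7 at 1.13 (camera adjusted p = 0.106). The Pax6 call held in 2 of 16 alternatives. Pax6 differed by -0.41 with the mean of its probe sets and by -0.13 without non-reactive replicate 1, where another probe set represented it and its first gave -1.29 without passing. With the mean of a gene's probe sets that list was called lower (0.0161, in a range of 0.0161 to 0.296). Of 23 phagocytosis and lipid handling genes Mertk, a phagocytic receptor, fell by 1.74 and Clu fell, against 3 risen and 3 fallen adjusted over the list alone, with Fabp5 at 0.08 (camera adjusted p = 0.698). No gene passed among 20 integrin genes (0.877, Cd81 at 0.03 and Itgav at -0.58), 18 glycan enzymes (0.877, Mgat4b at 0.05 and St6gal1 at -0.60) and 18 oxidative stress genes (0.352, Sod1 at -0.14 and Mt1 at -0.58), nor adjusted over the list alone. Of 17 synapse-regulating genes none passed and 1 fell adjusted over the list alone (camera adjusted p = 0.541, Sparcl1 at -2.66 with SE 0.45). For the integrin, glycan enzyme, phagocytosis and synapse lists camera's direction was down while the median log2 fold change was 0.16, 0.08, 0.05 and 0.05, and the mean was 0.13, 0.01, 0.16 and -0.18.

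Camera called 21 of the 37 lists, 14 higher and 7 lower, and no list held with an estimated correlation, where 11 had an unadjusted p under 0.05. Fry, which asks whether a list's genes move on balance in 1 direction, called 18 lists, and 30 for a change in either direction.

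**Figure D2:**
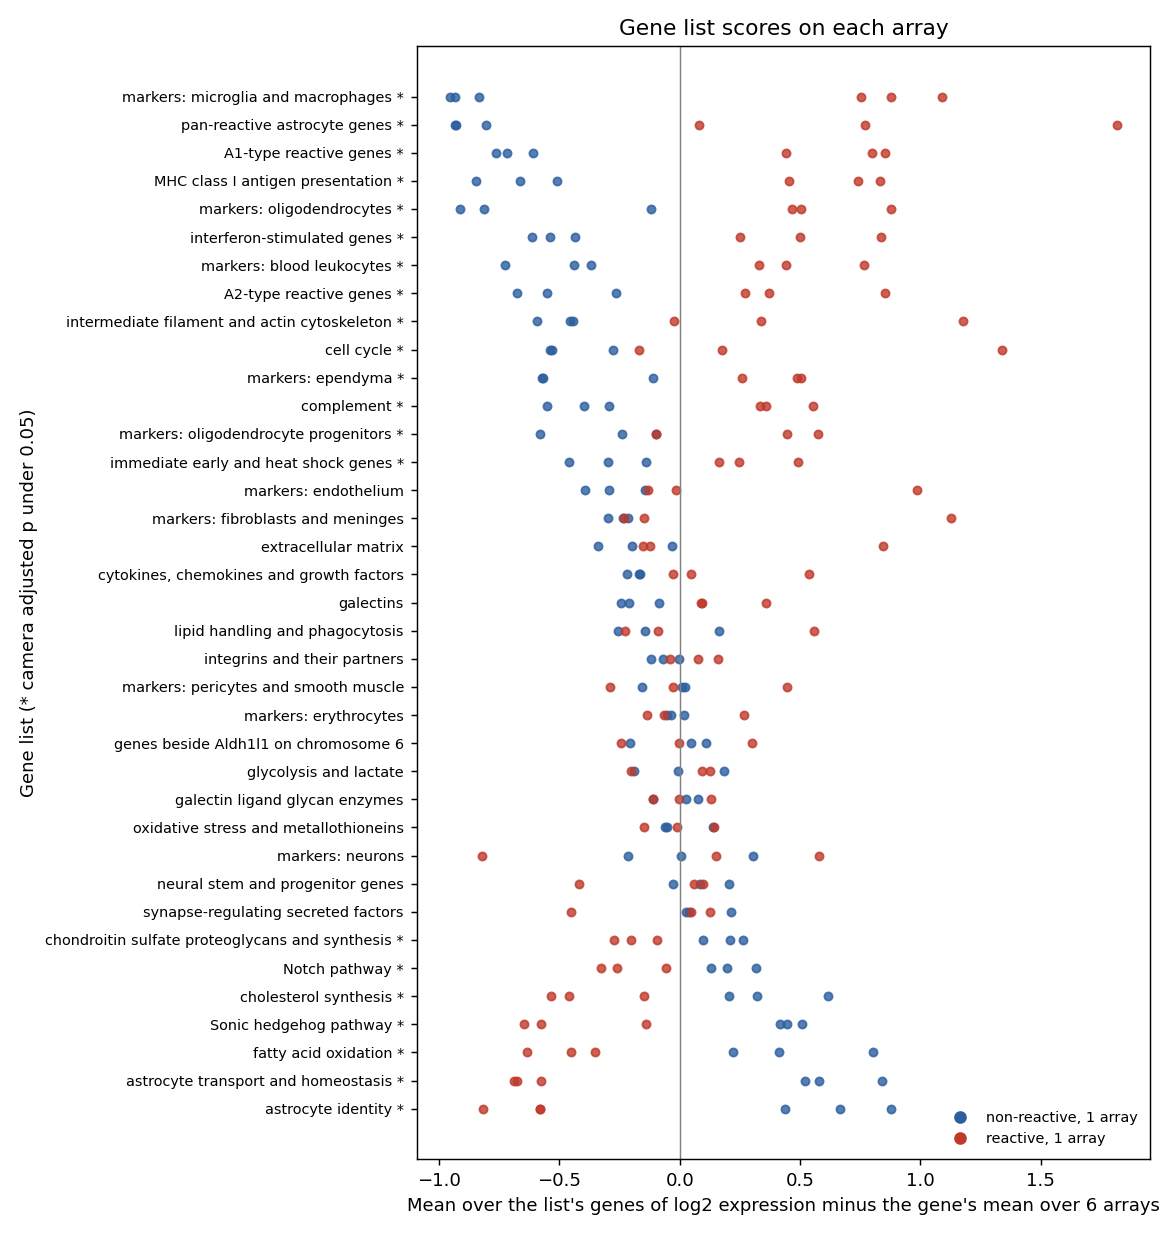
Gene list scores, the mean over a list's genes of log2 expression minus the gene's mean over the 6 arrays, with a point for each of the 3 non-reactive and 3 reactive arrays. The microglia and macrophage list lies at 0.75 to 1.09 in the reactive arrays and -0.96 to -0.83 in the non-reactive arrays.

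Control probe sets differed between the groups, and the cause was not tested. The 3′ minus 5′ difference of the Gapdh controls was 4.17 ± 0.41 in the reactive and 5.19 ± 0.50 in the non-reactive arrays, and that of the Actb controls 3.38 ± 0.87 and 5.05 ± 0.49 (log2, SD, n = 3). The difference of the Pcx controls was 1.44 ± 0.27 and 3.46 ± 0.04. That of the 18S rRNA controls went the other way, at 0.83 ± 0.27 and -1.15 ± 0.34, with the 5′ control at 10.24 ± 0.73 and 12.79 ± 0.28 and the 3′ control at 11.07 ± 0.47 and 11.64 ± 0.06. Each gave a two-sided exact permutation p of 0.1, the smallest that 3 arrays against 3 allow. Malat1, a nuclear long noncoding RNA chosen after its values were seen, fell by 1.96 at its probe set of highest mean. Its 7 probe sets ran from -1.43, without passing (limma adjusted p = 0.0571), to -4.14 (0.0249). Of the 9160 probe sets with no symbol 5 rose and 53 fell.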

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

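The alternative without myeloid markers was chosen after the results were seen. The 173 genes became 125 to 180 under the scaling, filter, variance, weight and probe set alternatives, which shared 98 to 157 genes with them. With 1 array left out, which also leaves fewer degrees of freedom, the counts of genes and of genes changed at least 2-fold ran from 0 (limma, 1898 to 2133 genes at an unadjusted p under 0.05) to 77. The test against 1.5-fold called 14. With the replicate number as a block, limma called 0 genes, and 0 changed at least 2-fold, with 2401 at an unadjusted p under 0.05, and 20 lists; Lgals3 stayed at 5.07 (adjusted p = 0.105, range 0.0282 to 0.138). The labels state no pairing of the replicate numbers. Deviations of same-numbered arrays correlated at -0.0726, -0.107 and 0.0371, and 0 of 3 reactive arrays matched their own number best. So few arrays cannot exclude a pairing. The standard error of the Lgals3 log2 fold change was 0.39 with the block and 0.67 without it, but the block leaves fewer degrees of freedom. With 1 array left out Lgals3 ran from 4.36 to 5.73, Lgals1 from 1.10 to 1.96 and the called lists from 19 to 23. Lgals1 has no value with the suffix filter for cross-hybridisation, which removed both of its probe sets through the suffix _a_at. This removal does not show that they read other genes. Camera with an estimated correlation called 0 lists, with 11 at an unadjusted p under 0.05, and fry 18; all 21 called lists kept their direction. Changes of sign were seen in genes and lists that did not pass, and the cause was not tested. With the mean of a gene's probe sets Lgals2 was 0.51, and relative to all genes the mean log2 fold change was 0.00904 for galectin ligand glycan enzymes and 0.0738 for erythrocytes. Without probe sets open to cross-hybridisation it was 0.0768 for glycolysis and 0.12 for erythrocytes, with quantile normalisation 0.00623 for erythrocytes and 0.0283 for genes beside Aldh1l1, with cyclic loess 0.0104 for the latter, and with dim probe sets dropped 0.0277 for the latter and 0.0195 for oxidative stress. With 1 array left out the ranges were -0.249 to 0.00983 for Lgals2, -0.193 to 0.0327 for Lgals7, -0.372 to 0.0287 for Lgals9, -0.00371 to 0.499 for extracellular matrix, -0.126 to 0.0549 for glycolysis, -0.133 to 0.253 for lipid handling, -0.419 to 0.279 for neurons, -0.17 to 0.19 for pericytes, -0.129 to 0.0745 for erythrocytes and -0.166 to 0.11 for genes beside Aldh1l1. Signal near background limits dim genes.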

Other observations

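All tests on the families, the sorted cells, the astrocyte genes and reactive replicate 3 were chosen after the results were seen, except the one on further myeloid genes, with its first filter, and the other splits of the arrays. Genes of mitochondrial ribosomal proteins were higher in the reactive arrays as a group. Of 76 measured genes 54 lay above the median of all genes, and 3 rose over all probe sets (limma), Mrpl20, Mrpl50 and Mrpl54. The median log2 fold change was 0.43 and camera gave an adjusted p of 1.07e-05 over 4 families, with an adjusted p = 0.282 with an estimated correlation. Cytosolic ribosomal proteins (0.0127) and NADH dehydrogenase subunits (0.0188) also passed with camera, both with an adjusted p = 0.282 with an estimated correlation, and both had 0.0953 after quantile normalisation, where the median of the NADH dehydrogenase subunits lay -0.00942 from that of all genes. Proteasome subunits did not pass with camera (0.0855), with an adjusted p = 0.471 with an estimated correlation. After cyclic loess they passed (camera, 0.0328). On the same reactive arrays microglia and macrophage markers (2.21e-14) and oligodendrocyte markers (1.03e-05) were called higher by camera. The 3′ minus 5′ difference of the controls differed by -1.03 for Gapdh, -1.66 for Actb, -2.02 for Pcx and 1.98 for 18S rRNA.

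Further genes, within and outside the lists, were chosen after their values were seen. The microglial gene Aif1 differed by 3.09 and Tmem119 by 1.19, while Siglech differed by 0.15, and none of them passed with limma. Of the cell cycle genes Cdc20 differed by 3.43, Cdk1 by 2.44 and Mki67 by 1.84, with the highest cell cycle score on reactive replicate 3. Aqp4, the astrocyte water channel, differed by -1.79 and Ntsr2 by -2.51. Xist, the transcript of the inactive X chromosome, measured 7.98 ± 2.69 in the reactive and 9.02 ± 3.02 in the non-reactive arrays (log2, SD, n = 3).

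Of 10 splits of the 6 arrays into 3 and 3, 1, the real one, called as many as 173 genes, and the highest of the others called 0 (limma, with up to 988 genes at an unadjusted p under 0.05). The splits are too few for a share under 0.05.

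Myeloid transcripts and Lgals3 were higher in the reactive arrays although dead cells, doublets and autofluorescent cells had been gated out and cells sorted for green fluorescence. A larger share of unchanged microglia would raise all markers alike only if each probe set responded equally. Over 15 bright markers the log2 fold changes had an SD of 1.03 against a median standard error of 0.31, from 0.04 for Cx3cr1 to 3.81. Probe sets of 1 gene spread too (Malat1 -1.43 to -4.14), so this spread cannot decide on a larger share, which stays open. A further 43 myeloid genes were listed, of which 38 were measured. The 15 with a mean of at least 7 over the 6 arrays had a median log2 fold change of 1.30, with 14 above 0.5. The median was 1.15 for the 10 with a non-reactive mean of at least 7 and 1.02 for all 38. Tested singly, 0 of the 38 passed (limma, 20 at an unadjusted p under 0.05). Activated microglia or macrophages among the sorted cells would raise these genes, but so would a larger share of unchanged microglia. The rise therefore cannot tell them apart, and both stay open. Lgals3 rose more than 9 of the 11 myeloid markers that passed, 6 of them by over 2 standard errors of the difference (Trem2 by 2.82, SE 0.98). It differed from Lyz1 by -0.79 (SE 0.67) and from Lyz2 by -0.60 (SE 0.57), near-identical genes that may give the same signal. The non-reactive mean of Lgals3, 4.92, lay close to 4.74, the median of all probe set means, so this order is uncertain. Since the markers rose by unequal amounts, Lgals3 RNA from myeloid cells and from astrocytes cannot be told apart, and expression by reactive astrocytes stays open, as untested.

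Astrocyte transport and identity genes were lower in the reactive arrays. Even dilution of astrocyte RNA by other cells would lower all alike only if each probe set responded equally. The 32 bright members ran from -3.07 to 0.05, with an SD of 0.86 against a median standard error of 0.34. Probe sets of 1 gene spread too (Malat1 -1.43 to -4.14), so this spread cannot decide on dilution, which stays open. More degraded RNA in the reactive samples would raise the 3′ minus 5′ difference of the controls, which differed by -1.03 for Gapdh, -1.66 for Actb and -2.02 for Pcx but by 1.98 for 18S rRNA, so it stays open. With 0 reporter lines present in both groups, astrocytes that differ between the lines and a response to injury cannot be told apart. Injury and line stay open.

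Reactive replicate 3 lay apart from the other reactive arrays. Its array weight was 0.716, and the lowest was 0.679, in reactive replicate 1. A poorer array and a pool that differed would both lower the weight, so they cannot be told apart. Vascular and connective tissue cells in that pool may contribute: 49 markers had a median 0.42 above the other reactive arrays, against -0.02 for all genes, with 15 above 1 and the highest at 4.39, a median between the bounds set for either outcome. At the probe set of highest mean, Xist measured 5.03 on it against 10.29 and 8.64 on replicates 1 and 2. Its other probe sets did not set it apart from replicate 2, at 3.66 and 3.95 against 3.82 and 4.05. They measured 6.52 and 4.69 on replicate 1. The Y-linked Eif2s3y measured 5.86 against 4.37 and 4.699, and 2.87 against 2.72 and 3.12 at its dimmer probe set. The dim Uty measured 3.11 against 3.06 and 3.43 at its probe set of highest mean. On non-reactive replicates 1, 2 and 3 Xist measured 6.05, 12.09 and 8.93 at its probe set of highest mean. There Eif2s3y measured 6.27, 4.57 and 5.60, and 2.55, 2.97 and 2.71 at its dimmer probe set. At their probe sets of highest mean, Eif2s3y was thus lowest where Xist was highest in each group. All were chosen after their values were seen. The sex of the pools was not determined and stays open, as untested.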
